A study of Mus musculus with 6 samples.

How the data were processed

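RNA from mouse embryonic stem cells of the E14 line was measured in 3 wild-type and 3 Pml knockout samples. Per the labels' protocols, polyadenylated RNA was made into libraries with an Illumina TruSeq RNA kit. Strandedness of the libraries and read length are not given in the sources used here. Per the series design text and the submitters' processing notes, reads were trimmed with cutadapt, aligned to mm10 with TopHat and tested with edgeR. The versions of these tools, the gene annotation, the read counter and the edgeR test are not given in the sources used here.

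The values come from 1 deposited table that holds 6 columns of CPM (reads of a gene scaled to the library's total), 1 per library, and a locus for most genes. Per the file headers, the authors also deposited a log2 fold change, an average log2 CPM, a p-value and an FDR per gene. The CPM columns were tied to samples by the genotype and replicate number in the column names. From the values, the deposited CPM are whole reads divided by the library's total, with no TMM scaling. In each library 100% of the values came out as whole reads within a tolerance of 0.01 of a read, and the recovered reads summed to the library total that the step implies. The recovered counts give library totals between 5845653 and 11046725 reads. In the smallest library 3 reads equal 0.513 CPM and in the largest 0.272 CPM, so differences among genes below about 1 CPM were not detectable at this depth unless they were large. Intervals of the share of the wild-type level kept, and floors, cover counting error only. The intervals come from reads pooled over the libraries of a group and leave out the spread between libraries. No source used here names molecular identifiers.

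Of 25833 rows, 1097 had no value in any library, of which 782 named no gene, and 315 repeated a gene with the same 6 values and were removed. This left 24421 genes, 6417 of them at 0 in all libraries. A spreadsheet had turned 27 symbols into dates, and these genes were kept without a name. Loci are given in mm10, from the deposited table where it gives 1 locus for a gene, with 1 added to the start because 6618 starts lay 1 base before those of GENCODE M21 against 659 at the same base. GENCODE M21 gave the chromosome of 849 further genes and the transcript length and GC content of 96.4% of the tested genes.

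Before averaging, libraries were compared by a chi-square over genes with at least 20 reads in a pair. The chi-square per degree of freedom was between 1.33 and 1.64 in the 6 pairs within groups and between 3.19 and 4.53 in the 9 pairs between groups. Every pair differed by more than sampling noise, and all 6 libraries were counted.

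The design was fixed before the data were examined, with 1 test for counts and another for normalized values. The table turned out to hold CPM, so limma 3.58.1 with an intensity trend was fitted to log2(CPM + 1) of all 6 libraries with no covariate. Genes were kept by edgeR's filterByExpr on the recovered reads, a choice of filter made after the unit was known, which left 12435 genes. Calls needed a Benjamini-Hochberg adjusted p under 0.05. The median log2 fold change of all tested genes was 0.00463. Because whole reads could be recovered, edgeR 4.0.16 (quasi-likelihood, TMM factors 0.997 to 1.003) was run on the recovered counts as an added alternative, and it called 1820 genes, 835 higher and 985 lower. Its common biological coefficient of variation was 0.0243.

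Gene lists fixed before the data were examined (26) and the chromosomes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists or chromosomes. Limma's fry, run as an alternative, tests whether a list's genes move on balance 1 way and compares them with no other genes. The Y-linked and 2-cell-stage lists hold with an estimated correlation at an adjusted p under 0.05, and the other 7 called lists do not; of the chromosomes, Y holds and 8 does not. The list of mitochondrially encoded transcripts was not analysed here. Named genes followed a rule fixed before the data were examined. It took Pml and all Y-linked genes of the list. Among called genes with no overlap between groups and a mean of at least 1 CPM in a group, leaving out symbols of the forms Gm with digits, Rik and LOC, it took the 10 highest, the 10 lowest and the 5 smallest p in each direction. In each list it took up to 4 called members with the largest absolute log2 fold change, or the 2 most abundant where none was called. Other genes named in the text, such as Pou5f1, Nanog, Mdm2, Mt1, Mt2, Pnma5, Erdr1 and the remaining called members of lists with few calls, were chosen after their values were seen.

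The pipeline was tested on simulated counts for this comparison, with 12460 genes tested and 50 genes changed at each of 4 fold sizes. It recovered 50% of genes changed 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 15 of 175 calls were false. Of 200 random lists 0 had a camera p under 0.05. The simulated genes varied independently of each other, so this does not show how camera treats lists whose genes vary together.

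Alternatives covered the pseudocount, the filter, the test (DESeq2 1.42.0 and edgeR on recovered counts), size factors, the adjusted p threshold, each library left out in turn, the replicate number as a block, GC content and length, and the set test. R 4.3.3 and Python 3.11.15 were used.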

Results

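Polyadenylated RNA was sequenced from E14 cells, an embryonic stem cell line from a male mouse, grown with serum, leukemia inhibitory factor and inhibitors of GSK3 and MEK. The 6 libraries fell into 2 groups, 3 of wild-type cells and 3 of Pml knockout cells. Pml encodes the scaffold protein of PML nuclear bodies, which are protein assemblies in the nucleus that hold many SUMO-modified proteins. The comparison asks which transcripts differ in level between embryonic stem cells with and without an intact Pml gene. The wild-type libraries held 11046725, 10325194 and 9389186 counted reads (replicates 1, 2 and 3), and the knockout libraries held 7584503, 5845653 and 8693079. Levels are given as CPM, the reads of a gene scaled to its library's total, as mean ± SD over n = 3 libraries per group. Log2 fold changes, knockout over wild type, are on the log2(CPM + 1) scale, which understates the change of genes with low values. The labels do not say that the replicates came from separate cultures or separate knockout clones, and the deposited names of the 3 knockout columns share 1 prefix, KO34, as those of a single line would, so p-values measure only the spread between these libraries, which may be technical.

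Pml itself (mm10, chromosome 9, 58217180 to 58251503) stood at 191 ± 4.09 CPM in wild-type cells and at 76.3 ± 0.912 CPM in knockout cells. Its log2 fold change was -1.31 (SE 0.0412, limma adjusted p = 1.28e-20), and the 3 knockout libraries all lay below the 3 wild-type libraries. The knockout group kept 40% of the wild-type level (exact 95% interval 37.9% to 42.2% from 1690 and 5876 reads, counting error only). The labels do not state which part of Pml was disrupted, so reads outside that part may remain in the count.

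In the knockout, transcripts of Y-linked genes fell to near 0 and 2-cell-stage genes rose, while genes of an X-linked cluster and 12 of 26 imprinted genes fell. Of 12435 genes tested with limma, 813 were higher and 932 lower in the knockout at an adjusted p under 0.05. Most differences were small, with a median absolute log2 fold change of 0.273 among the called genes. An absolute log2 fold change of at least 1 was reached by 25 of the higher and 56 of the lower genes, and 24 of the lower genes reached at least 2. The groups did not overlap for 30.2% of the tested genes, against 10% given by chance for 3 against 3 libraries. Without wild-type replicate 2, 1160 genes were called, of which 512 were higher. With no filter on low values 364 genes were called (118 higher, 246 lower), and DESeq2 on recovered reads called 802 (334 higher, 468 lower).

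All 5 tested Y-linked genes of the list fell to near 0 in the knockout. Ddx3y, which encodes an RNA helicase, went from 91.7 ± 5.26 to 0.869 ± 0.189 CPM (log2 fold change -5.64, SE 0.111, limma adjusted p = 1.2e-25). Eif2s3y, a subunit of a translation initiation factor, went from 73.2 ± 0.383 to 0.553 ± 0.32 CPM. Uty, a relative of the histone demethylase Kdm6a, went from 27.4 ± 1.96 to 0.152 ± 0.174 CPM, and Uba1y, a ubiquitin-activating enzyme, from 45.3 ± 2.95 to 0.892 ± 0.262 CPM. These genes kept 0.939%, 0.803%, 0.497% and 1.99% of the wild-type level. Zfy1 had 111 reads over the wild-type libraries and 0 over the knockout libraries, which makes it at least 26.6-fold lower against a floor of 3 reads over the group. Kdm5d, with 20 wild-type reads, and Zfy2, with 18, also had 0 reads in the knockout, at least 4.79-fold and at least 4.32-fold lower, and were below the filter of the test. Usp9y had 2 reads in wild type and 0 in the knockout, Sly had 0 and 2, and Sry, Rbmy, Ssty1 and Ssty2 were at 0 in both groups. The median log2 fold change of the 5 tested genes was -4.63, and all 5 also passed when adjusted over the list alone (camera adjusted p = 3.85e-28). With an estimated correlation the adjusted p was 0.00411. On the scale of the plain ratio of reads per library total, with Zfy1 at the floor, the median log2 ratio was -6.73. The listed genes with reads in wild-type cells lie between 725100 and 2170409 on chromosome Y, from Zfy1 to Zfy2.

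**Figure D1:**
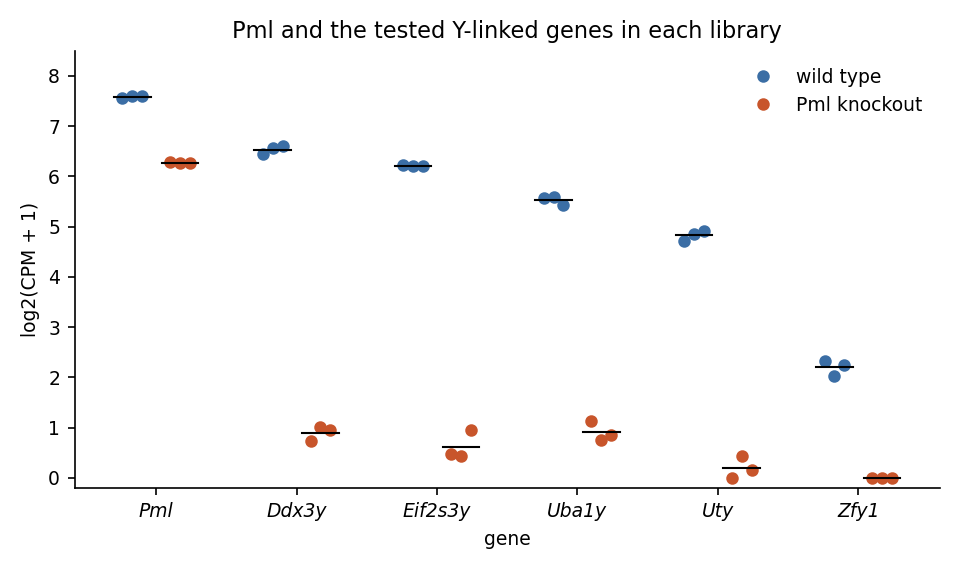
Level of Pml and of the 5 tested Y-linked genes on the log2(CPM + 1) scale, with 1 point per library and a line at the mean of the 3 libraries of a group. Pml kept 40% of its wild-type level, whereas Ddx3y, Eif2s3y, Uba1y and Uty kept at most 1.99%, and Zfy1 had 0 reads in each knockout library.

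Among the X-linked partners of Y-linked genes, 2 of 9 were higher in the knockout and the other 7 did not pass the test (2 when adjusted over the list alone; camera adjusted p = 0.187). Ddx3x rose from 614 ± 16.1 to 684 ± 18 CPM (log2 fold change 0.15, SE 0.0284, limma adjusted p = 0.000275), and Usp9x was the other.

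Genes transcribed at the 2-cell stage of the mouse embryo, which a small fraction of embryonic stem cells also transcribes, rose together. Of 21 tested members 19 were higher, or 20 when adjusted over the list alone, with a median log2 fold change of 1.15 (camera adjusted p = 7.45e-30, or 0.00411 with an estimated correlation). Zscan4f, a zinc finger gene that marks this state, rose from 17.9 ± 1.56 to 48.3 ± 3.02 CPM (log2 fold change 1.39, SE 0.0782, limma adjusted p = 2.51e-14). Zscan4c rose from 19.05 ± 1.79 to 48.2 ± 3.01 CPM, and Zscan4a, Zscan4b and Zscan4d had log2 fold changes of 1.36, 1.31 and 1.31. The deubiquitinase genes Usp17le, Usp17lc and Usp17la, and the transcript BB287469, had log2 fold changes between 1.15 and 1.31. These genes and Spesp1, which encodes a sperm equatorial segment protein (log2 fold change 1.10), were the 10 highest of the called genes that met the naming rule. Zscan4 and Usp17l are families of near-identical copies, Zscan4a, Zscan4b and Zscan4c share 1 locus in the deposited table, and the split of reads between copies is uncertain. With 1 gene kept per family name and locus, 11 of 12 were higher.

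A cluster on chromosome X was lower in the knockout. All 12 tested genes from Pnma5 to Xlr5c (73033981 to 73290515) fell, a region singled out after its values were seen. Xlr3a, of a family of lymphocyte-regulated genes, went from 32.8 ± 3.08 to 1.33 ± 0.817 CPM (log2 fold change -3.92, SE 0.179, limma adjusted p = 1.65e-16). Xlr3c, Xlr5a and Xlr5b had log2 fold changes of -3.43, -3.33 and -3.20, and Pnma5 next to the family had -2.43. Most of these genes share the locus from 73086293 to 73265390 and are close copies, so the split between them is uncertain. Elsewhere on chromosome X, Efhc2 went from 15 ± 1.56 to 0.0823 ± 0.0718 CPM. Alg13, which acts in N-linked glycosylation, fell from 340 ± 6.39 to 95.2 ± 2.56 CPM (log2 fold change -1.83, SE 0.0371, limma adjusted p = 1.2e-25).

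Imprinted genes are transcribed from 1 parental allele. Of 26 tested, 12 were lower, 2 were higher and 12 did not pass; adjusted over the list alone, 14 were lower and 3 higher (camera adjusted p = 2.43e-07). The list's adjusted p was 0.074 with an estimated correlation. Plagl1, a zinc finger regulator of growth, fell from 158 ± 7.37 to 14.19 ± 1.71 CPM (log2 fold change -3.39, SE 0.0687, limma adjusted p = 1.2e-25). Peg12 fell by 1.76 on the log2 scale. The neighbours H19 and Igf2 moved apart: H19 went from 2.18 ± 0.312 to 0.613 ± 0.546 CPM, and Igf2, a growth factor gene, from 1.94 ± 0.359 to 5.07 ± 0.825 CPM. Grb10 was the other imprinted gene that rose (log2 fold change 0.43).

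**Figure D2:**
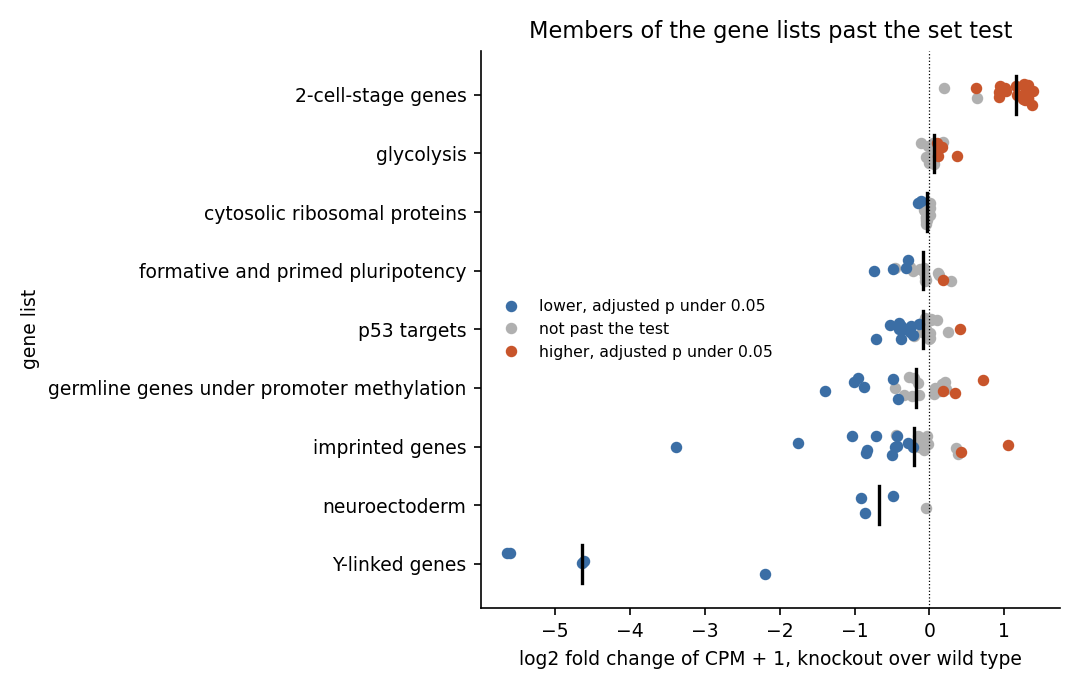
Log2 fold change of CPM + 1, knockout over wild type, of each tested member of the 9 gene lists past the set test, with 1 point per gene and a line at the list median. The 2-cell-stage genes have a median of 1.15 and the Y-linked genes one of -4.63, and the other 7 lists lost the set call with an estimated correlation.

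The genes of the DNA methylation machinery moved in both directions, with 5 of 17 higher, 4 lower and 8 not past the test (5 and 6 when adjusted over the list alone; camera adjusted p = 0.921). Tet3, a dioxygenase that oxidizes methylated cytosine, fell from 12.9 ± 0.265 to 6.27 ± 0.489 CPM, and Dppa3, which protects methylation in the early embryo, from 2.56 ± 0.465 to 0.792 ± 0.54 CPM. Dnmt3b, a de novo methyltransferase, fell by 0.32 and Dnmt1 by 0.09 on the log2 scale, whereas Tet1, Tet2, Dnmt3l, Mbd4 and Zfp57 rose by 0.31, 0.18, 0.21, 0.23 and 0.20. The list's median was 0.05 and its mean -0.07. Germline genes under promoter methylation had 6 of 22 lower, 3 higher and 13 not past the test (8 and 3 when adjusted over the list alone). Their camera adjusted p was 0.0083, and the adjusted p was 0.161 with an estimated correlation and 0.179 with no filter on low values. Hormad1, which acts on meiotic chromosome axes, fell from 26.5 ± 1.97 to 9.56 ± 1.95 CPM, and Smc1b, Tuba3a and Tuba3b fell by 1.01, 0.95 and 0.88 on the log2 scale. Sycp1, Sycp3 and Rpl10l rose by 0.71, 0.34 and 0.18.

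Naive pluripotency genes did not pass as a group (camera adjusted p = 0.068): 5 of 25 were higher, 4 lower and 16 not past the test, or 8 and 4 when adjusted over the list alone. The list passed without wild-type replicate 1 (adjusted p = 0.0256), with the replicate number as a block (0.0226) and after a correction for GC content and length (0.0102). With an estimated correlation its camera adjusted p was 0.323. The core factor Pou5f1 stood at 1447 and 1457 CPM in wild-type and knockout cells, and Nanog at 1002 and 1045 CPM; neither passed the test. Tdgf1, a Nodal co-receptor, rose by 0.35 on the log2 scale, and Klf4, Tfcp2l1, Tbx3 and Nr0b1 also rose, whereas Gbx2, Tcl1, Klf5 and Sall4 fell. Formative and primed pluripotency genes had 4 of 17 lower and 1 higher (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0343, or 0.228 with an estimated correlation). Lef1, Sall2, Dnmt3b and Zic2 fell by 0.74, 0.49, 0.32 and 0.29 on the log2 scale, and Nodal rose by 0.19. The list's adjusted p was over 0.05 without wild-type replicate 1, without wild-type replicate 3 and without knockout replicate 2, with 0.0632 as the highest, and it was 0.0582 with the replicate number as a block. It was also over 0.05 with no filter on low values and with edgeR or DESeq2 on recovered reads.

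Markers of the nervous system precursor lineage fell in 3 of 4 tested genes, also when adjusted over the list alone (camera adjusted p = 4.4e-05, or 0.074 with an estimated correlation and 0.166 with no filter on low values). Nes, an intermediate filament of neural precursors, fell from 29 ± 2.97 to 15.5 ± 1.246 CPM. Sox1 and Tubb3, which both lie on chromosome 8, fell by 0.91 and 0.49 on the log2 scale. Primitive endoderm genes had 2 of 9 higher (3 when adjusted over the list alone), the laminin genes Lamb1 and Lamc1, with log2 fold changes of 0.60 and 0.23 (camera adjusted p = 0.0993). Their median was -0.02, below 0, while the mean and the direction of the test were above 0. Camera compares a list with the other genes, whereas fry asks whether a list's genes move on balance 1 way, without such a comparison; by fry the adjusted p of this list was 0.0136. Mesoderm genes (1 higher, Eomes, and 1 lower, Bmp4, of 7, also when adjusted over the list alone; camera adjusted p = 0.921) did not pass as a group. Neither did trophoblast genes (1 higher and 2 lower of 12, or 4 and 2 when adjusted over the list alone; 0.93), of which Cdh3, on chromosome 8, fell by 1.01 and Cdx2 by 0.54, and Eomes rose by 0.27. Fibroblast markers, which feeder cells would carry, had 2 higher and 2 lower of 8, also when adjusted over the list alone. Their camera adjusted p was 0.93, with a median of 0.12 and a mean of -0.06. By fry, the test without a comparison to other genes, the adjusted p was 0.0256, with the direction down in the knockout. Thy1 and Vim fell by 0.95 and 0.46 on the log2 scale, and Pdgfrb and Fn1 rose by 0.39 and 0.30. Of 2 blood cell markers tested, Cd68 stood at 16.4 and 13.9 CPM and Cd3e at 3.25 and 3.75 CPM, and neither passed limma, edgeR or the adjustment over the list alone (1 had an unadjusted p under 0.05; camera adjusted p = 0.895). Without knockout replicate 1, Cd68 had a limma adjusted p of 0.049.

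Of 27 tested targets of the tumour suppressor p53, 11 were lower, 1 was higher and 15 did not pass the test (12 lower and 1 higher when adjusted over the list alone). The camera adjusted p was 6.45e-05, and the adjusted p was 0.0672 with an estimated correlation. The cell cycle inhibitor Cdkn1a fell from 210 ± 4.91 to 158 ± 4.67 CPM (log2 fold change -0.40, SE 0.0374, limma adjusted p = 3.13e-09). Pmaip1 and Bbc3, which promote cell death, fell by 0.71 and 0.53 on the log2 scale, while Mdm2 stood at 125 and 126 CPM in wild-type and knockout cells. In the PML body and SUMO pathway list, 4 of 34 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.278). Sumo3 fell by 0.26 and the SUMO protease Senp2 by 0.28, and Sp110, Atrx, Pias2 and Senp3 rose by 0.77, 0.18, 0.11 and 0.09. Interferon-stimulated genes had 2 higher and 3 lower of 22 (2 and 4 when adjusted over the list alone; camera adjusted p = 0.657), of which Stat2 and Ifitm2 rose by 0.38 and 0.17, and Tap1, Bst2 and Oas1a fell by 0.75, 0.49 and 0.25.

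Of 21 glycolysis genes 5 rose and 16 did not pass the test, or 7 rose when adjusted over the list alone (camera adjusted p = 0.00101, or 0.64 with an estimated correlation). The glucose transporter Slc2a3 rose from 1739 ± 19.4 to 1951 ± 69.4 CPM and Aldoc, Pfkl, Gpi1 and the pyruvate kinase Pkm by 0.37, 0.13, 0.12 and 0.10 on the log2 scale. Without knockout replicate 1 the list's adjusted p was 0.287. By fry, against no change, it was 0.338. Cytosolic ribosomal protein genes had 2 of 31 lower, Rpl13 and Rps23, by 0.15 and 0.11, also when adjusted over the list alone (camera adjusted p = 0.00101, or 0.65 with an estimated correlation and 0.343 after a correction for GC content and length; by fry, against no change, 0.213). Cholesterol synthesis genes had 3 of 23 lower (4 lower and 3 higher when adjusted over the list alone; camera adjusted p = 0.851; median 0.05, mean -0.01). Hmgcs1, the synthase that makes the precursor of mevalonate, fell from 301 ± 11.8 to 198 ± 2.25 CPM, and Insig1 and Sc5d fell by 0.40 and 0.31. Oxidative phosphorylation genes had 1 higher and 1 lower of 29, also when adjusted over the list alone (camera adjusted p = 0.187), which were Ndufb10, by 0.19, and Atp5c1, by 0.25. That list passed without knockout replicate 2 (adjusted p = 0.0315). MEK/ERK feedback targets had 1 lower of 13, Etv4, by 0.62, also when adjusted over the list alone (0.271). Wnt targets had 2 higher, Notum and Apcdd1, and 4 lower of 16, which were Lef1, Cdx2, Tnfrsf19 and Sp5 (3 and 5 when adjusted over the list alone; 0.151). Mitosis genes had 1 higher and 1 lower of 20, also when adjusted over the list alone (0.93), with Cdc20 lower by 0.12 and Top2a higher by 0.09. Of 2 replication-dependent histone genes tested, Hist1h2bc stood at 5.21 and 5.68 CPM and Hist1h1c at 3.30 and 2.63 CPM, and 0 passed limma, edgeR, an unadjusted p of 0.05 or the adjustment over the list alone (camera adjusted p = 0.921).

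By chromosome, the genes of chromosome 8 and of chromosome Y were lower as sets. On chromosome 8, 92 of 663 tested genes were lower and 17 higher, 66.8% of the log2 fold changes lay below 0, and their median was -0.05 (camera adjusted p = 0.000544, or 0.057 with an estimated correlation). Among its called genes were Sox1, Tubb3, Cdh3, Rpl13 and the metallothionein genes Mt1 and Mt2, which fell by 0.66 and 0.71 on the log2 scale. Of 7 genes tested on chromosome Y, 5 were lower and 1 was higher (camera adjusted p = 1.08e-18, or 0.0147 with an estimated correlation and 0.0501 with no filter on low values). The higher one, Erdr1, lies in the pseudoautosomal region shared with chromosome X. Chromosome X had 49 higher and 47 lower of 434 genes and did not pass (0.932). Without the genes of chromosomes 8 and Y, 795 genes were higher and 835 lower.

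**Figure D3:**
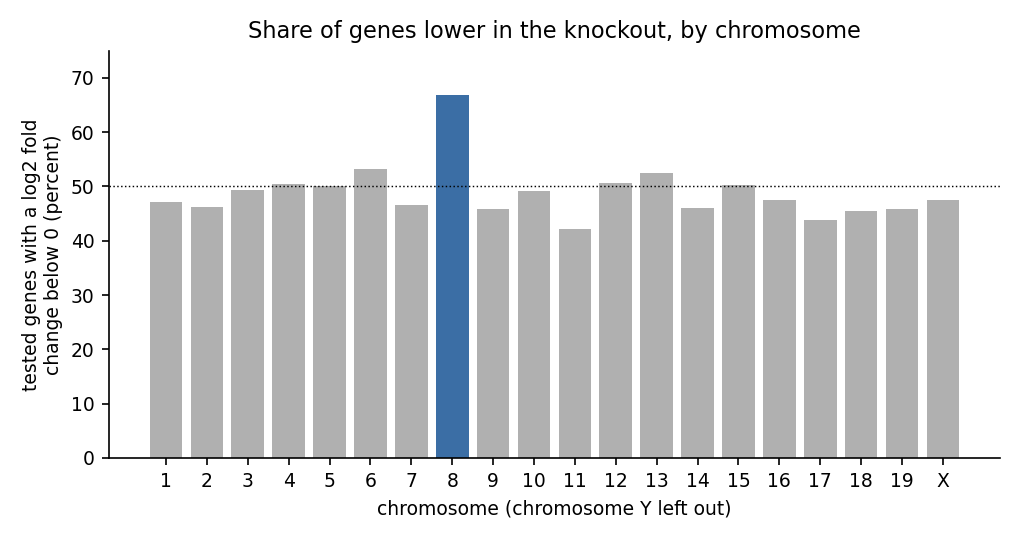
Percent of the tested genes on each chromosome with a log2 fold change below 0, knockout over wild type, with chromosome Y left out and a dotted line at 50. On chromosome 8 the share was 66.8% of 663 genes, and on chromosome X it was 47.5% of 434.

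For 16 named genes the call was lost when a library was left out, while the log2 fold change kept its sign. All but Oas1a and Aldoc lost it in more than 1 of these fits. Some log2 fold changes moved by over 1.5 times: without knockout replicate 1, those of Pfkl, Gpi1 and Aldoc went from 0.13, 0.12 and 0.37 to 0.07, 0.08 and 0.25, and that of Bbc3, which kept its call, from -0.53 to -0.32. That of Atrx went from 0.18 to 0.10 without wild-type replicate 2, and that of Pdgfrb from 0.39 to 0.25 without knockout replicate 2. Without wild-type replicate 1, Usp9x, Gbx2, Bst2, Rrm2b, Eomes, Ndufb10 and Sc5d had limma adjusted p values between 0.0626 and 0.136. Leaving out wild-type replicate 2 gave 0.0577 to 0.231 for Usp9x, Sp110, Atrx, Gbx2, Bst2, Bmp4, Eomes, Ndufb10, Pfkl and Top2a. Leaving out wild-type replicate 3 gave 0.0545 to 0.159 for Sp110, Rrm2b, Bmp4, Eomes, Pdgfrb, Pfkl, Gpi1, Sc5d and Top2a. For knockout replicate 1 the range was 0.0523 to 0.288 over Usp9x, Rrm2b, Eomes, Aldoc, Pfkl and Gpi1. For knockout replicate 2 it was 0.0549 to 0.113 over Oas1a, Bmp4 and Pdgfrb, and for knockout replicate 3 it was 0.0531 to 0.225 over Usp9x, Sp110, Atrx, Gbx2, Bst2, Rrm2b, Eomes, Ndufb10, Pfkl and Top2a.

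The authors' deposited table gives 628 higher and 926 lower genes at an FDR under 0.05. Of the 1745 genes called with limma, 1497 were also called in the authors' deposited table with the same sign, 248 were not, and 0 were called there with the opposite sign. Of the authors' calls, 28 did not pass limma and 29 lay outside the genes tested.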

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

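Added after the data were seen were edgeR with TMM on recovered reads, limma on TMM-scaled CPM, the correction for GC content and length, the count without chromosomes 8 and Y, and the 2-cell-stage list thinned by family. No result reversed, and Pml stayed lower with a call in every fit run. The 1745 calls (813 higher, 932 lower) became 364 (118 and 246) with no filter on low values, where 24421 genes were tested, and 802 (334 and 468) with DESeq2; the cause was not tested. By construction, the adjusted p under 0.01 gave 916 (382 and 534), and an added absolute log2 fold change of at least 1 gave 81 (25 and 56). With 1 library left out the count ranged from 1160 to 1852, the higher genes from 512 to 872 and the lower from 632 to 980. The lowest total and the 512 came without wild-type replicate 2, and the 1852 without knockout replicate 2. Equally many libraries remain in each of these fits, and the cause was not tested. The other alternatives stayed within 1.5 times, with 1820 calls by edgeR (1721 shared with the same sign), 1734 on TMM-scaled CPM and 1760 after the GC and length correction, where 50.9% of calls were higher against 46.6%. With no filter, 32.4% were higher. Camera called 9 lists, and 2 with an estimated correlation; it called 2 chromosomes, and 1 with no filter, where chromosome Y had an adjusted p of 0.0501. The labels do not say whether same-numbered libraries share more than a number. The correlations of their deviations were 0.0755, 0.0603 and 0.0136, each the highest for its libraries, a hint from the data and not the design. The replicate block gave 2337 calls (1138 and 1199), with all 1745 among them; under it the naive pluripotency list passed (0.0226) and the formative list did not (0.0582). Of 1742 alternative values of the 83 called named genes other than Pml, 1620 kept call and direction, 122 lost the call and 0 reversed. Of these genes 46 lost the call under some alternative and 16 when a library was left out. Genes outside the 16 that lost it with no filter on low values were Usp17le, Usp17la, Spesp1, Ddx3x, Senp2, Dppa3, Dnmt3b, Tet1, Tdgf1 and Tcl1. The same held for Lef1, Sall2, Zic2, Smc1b, Tuba3b, Peg12, Igf2, H19, Tap1, Stat2 and Bbc3. It also held for Lamc1, Sox1, Cdx2, Fn1, Atp5c1, Slc2a3, Rpl13, Rps23 and Sp5, and the highest limma adjusted p was 0.388, for Bbc3. Alternatives planned for a table with no values per library were not run. Libraries of 5845653 to 11046725 reads limit what can be said of genes under 1 CPM.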

Other observations

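Chosen after the result was seen were the tests of Y chromosome loss and silencing, of the separate pairs of Y-linked and X-linked genes and of methylated regions, the GC content and length correction, and the genes of the next paragraph.

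The neurofilament gene Nefm went from 24.9 ± 0.89 to 3.98 ± 0.345 CPM and Nefl from 58 ± 2.24 to 19.2 ± 0.777 CPM (limma adjusted p = 6.11e-16 and 1.29e-16). In the Dlk1-Dio3 imprinted region on chromosome 12, the non-coding Rian and Mirg fell by 0.28 and 0.49 on the log2 scale, whereas Dio3 rose from 3.52 ± 0.147 to 6.96 ± 0.659 CPM. The non-coding Meg3 of that region did not pass (log2 fold change -0.21, limma adjusted p = 0.0716). Dlk1, at 0.815 and 0.812 CPM, was below the filter of the test. The placental homeobox gene Rhox5 fell by 1.77 and the class II antigen gene H2-Eb1 by 2.62. The ribosomal RNA precursor Rn45s, whose level depends on how polyadenylated RNA was selected, stood at 1738 ± 25.6 and 1336 ± 87.2 CPM. Actb stood at 2099 ± 42.7 and 1526 ± 23.7 CPM, and both were lower in the knockout. Whether the selection of RNA differed between the groups was not tested, a limit that holds for the other calls too. Gapdh stood at 6107 ± 51 and 6100 ± 210.1 CPM and did not pass the test.

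With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For gene calls, 1 of the 10 splits, the real one, gave as many as 1745, and the highest other gave 0 with limma and with edgeR (at most 491 at an unadjusted p under 0.05). For gene lists, 1 split gave as many as 9, and the highest other gave 5. For chromosomes, 1 split gave as many as 2, and the highest other gave 1. Every other split mixes wild-type and knockout libraries unequally, so part of the genotype difference remains between its groups. The rest adds to the spread within its groups, which lowers gene calls. These splits therefore do not measure false calls of genes, lists or chromosomes.

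The Y-linked genes fell to near 0 in all 3 knockout libraries. Assignment of their reads to X-linked partners is argued against by a summed gain of 0.31 of the loss (upper bound 0.435). Taken pair by pair, it is argued against for Uty, Eif2s3y and Uba1y, with gains of 0.193, -0.233 and 0.121 of the loss (upper bounds 0.315, -0.128 and 0.481). The gains cannot decide for Ddx3y, Zfy1 and Kdm5d, at 0.768, 0.824 and 11.7, since their upper bounds (1.07, 1.8 and 30.7) exceed the loss. For Kdm5d the SE of the Kdm5c gain, 6.22 CPM, exceeds the loss of 0.652 CPM. The same processing is described for both groups, and in wild type it gave Ddx3y 2813 reads and Zfy1 111. This argues against such an assignment in the knockout alone for these 2 genes, and Kdm5d has too few reads to tell. Loss of the Y chromosome and silencing on a Y chromosome that is kept cannot be told apart, since both would bring the Y-linked genes near 0. Erdr1 was left out here because its region is shared with chromosome X. Outside that region and the list, 1 other Y-chromosome locus had enough reads. This locus, Gm20871, kept 53.3% (exact 95% interval 29.1% to 93.4%, 47 and 18 reads). Gm20871 is multi-copy and its reads may come from copies elsewhere, so its level cannot decide between loss and silencing. Loss of only the part that holds the listed genes was not tested, and DNA was not analysed here.

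Genes of chromosome 8 were lower by a small amount. GC content or transcript length is argued against, since the median log2 fold change after that correction was -0.0429 (bootstrap SE 0.00647) against -0.000209 for the next lowest autosome. In 12 of 12 windows of 10 Mb with at least 20 tested genes the median was below 0, from -0.109 to -0.0252, which restates the pattern. A difference between the groups in copies of chromosome 8 and regulation of many genes along it both stay open, and neither was tested. The comparison is relative and does not tell in which group chromosome 8 changed.

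Of 26 imprinted genes tested, 12 were lower and 2 higher (camera adjusted p = 0.074 with an estimated correlation). GC content or transcript length is argued against, as 14 of the 14 called genes kept call and sign after the correction. Gain of DNA methylation at regions normally methylated on the maternal allele stays open: 7 of 11 tested genes with a promoter in such a region fell, against 5 of the 15 other imprinted genes. The difference between these shares did not pass a two-sided Fisher's exact test (p = 0.233, odds ratio 3.32, 95% interval 0.533 to 24.4), so with these few genes it did not decide. The other genes include H19, Rian and Mirg, which also fell, and whether methylation elsewhere acts on them was not tested. Methylation was not analysed here, and a difference between clones that does not depend on Pml stays open for this and the other patterns.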
